A study of Mus musculus with 2 samples.

How the data were processed

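Small RNA libraries from female mouse adrenal gland at 14 days were used, 1 group of 2 biological replicates by the labels. The labels give a size range below 30, with no unit, and a protocol for multiplexed miRNA libraries. For each library the authors deposited raw counts per miRNA gene, as whole numbers that are not normalized. Per the text files deposited beside the tables, the genome build was mm10, the annotation GENCODE M21, and each table came from reads of 1 library. The aligner, the counter, adapter trimming and their settings are not given in the sources used here. The tables have no header, and hold 4 leading summary lines (unmapped, mapping to several places, no feature, ambiguous) and then 2202 genes with 3 count columns. All 2202 gene identifiers matched miRNA genes of GENCODE M21, from which symbols, coordinates, host genes and hairpin sequences were taken.

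The columns are not defined in the sources used here, so their meaning was taken from the values. By a rule set before the data were examined, the main column was the strand column with more counts over miRNA genes in both libraries, read as the gene's own strand. The opposite-strand column held 960065 and 1162544 counts, nearly all at the 64 genes with an annotated miRNA gene on the other strand. Counts are per precursor gene, so the 2 arms of a hairpin are not told apart. Reads that map to several places were set aside by the authors' counting, as the summary lines show, so the values of genes with near-identical copies are uncertain. The summary lines stayed out of library sizes. Unmapped reads made up 26.9% of replicate 1 and 23.9% of replicate 2, reads mapping to several places 28.0% and 25.0%, and reads on no feature 9.65% and 6.12%.

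From these counts, CPM and percent shares were computed over all miRNA genes, with the mean and SD of 2 libraries. A gene was detected with at least 10 counts in each library. Shares of a single library carry Wilson 95% intervals. A chi-square test over genes with an expected count of at least 5 tested whether the libraries agree within sampling noise. Log2 ratios are replicate 2 over replicate 1, with TMM factors (1.16 and 0.862) and a prior count of 0.5. Their intervals are exact Clopper-Pearson 95% intervals of the binomial share. Each detected gene had an exact two-sided binomial test with Benjamini-Hochberg adjustment, a threshold of 0.05 and an absolute log2 ratio of at least 1. The biological coefficient of variation came from edgeR with an intercept-only design. With 1 library on each side, no quasi-likelihood test across replicates of 2 conditions applied. Correlations used log2 of CPM plus 1.

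Before the data were examined, 18 gene lists were fixed: let-7, Mir17 to Mir92, smooth muscle and stromal, endothelial, leukocyte, erythroid, striated muscle, liver, kidney and gut, miR-200, neuronal, neuroendocrine, steroidogenic, Dlk1-Dio3, other growth loci, Mir322 cluster, miR-506 and hypoxia. Mir34a and Mir150 each stand in a pair of lists. A list with at least 3 detected members was placed by its median log2 ratio among 10000 seeded random lists of equal size, drawn from pools of 20 genes of nearest expression. The rule for named genes was also fixed then. It takes the 12 genes of highest mean CPM and up to 3 most abundant members of each list. Among genes with a mean of at least 100 counts and an adjusted p under 0.05, it adds the 8 largest and 8 smallest log2 ratios. Further list members and the copy Mir26a-2 were named after their values had been seen.

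The statistics were tested on simulated data drawn from the real genes and depths. With counting noise alone, 0 of 372 genes were called. With 200 genes changed, again under counting noise alone, 353 were tested. Of 36 genes changed by a log2 ratio of 1.5, 91.7% were called in the right direction, and of 37 changed by 3, 100% were. Of 280 unchanged genes, 0 were called. Both simulations lacked spread between replicates beyond counting, while the real libraries had a coefficient of variation of 0.444. They therefore do not show how many calls such spread produces. A simulated coefficient of variation of 0.5 was estimated as 0.502 over 355 genes. Of 200 random lists of independently simulated genes, 4.5% fell outside the percentile limits.

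Alternatives fixed before the data were examined were the unstranded column, count minimums of 1 and 100, DESeq2 size factors, library totals alone, each replicate left out, the most abundant gene left out, numbered gene copies left out, pseudocounts of 0.1 and 10 CPM, a prior count of 5, thinning of the deeper library, DESeq2's dispersion, and edgeR's exact test with the estimated dispersion. Leaving out Mir122, and leaving out the 8 genes raised most, were added after seeing the data. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.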

Results

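MicroRNA levels were measured by small RNA sequencing in adrenal glands of female mice at 14 days of age. The animals were B6CASTF1/J, the F1 hybrid of a C57BL/6J and a CAST/EiJ parent. MicroRNAs are short RNAs, processed from hairpin precursors, that repress messenger RNAs by base pairing. The series holds 1 group of 2 libraries, labelled as biological replicates 1 and 2, so no comparison between conditions can be made. The label of replicate 1 speaks of 3 females and that of replicate 2 of a single numbered female, while both carry the same donor identifier. The replicates are compared below only to measure how far values of this tissue differ between libraries. The p-values of the binomial test measure only departure from counting error between these 2 libraries, not the spread between animals. Other p-values are given with the test they come from. Replicate 1 held 10720796 reads, of which 3797107 (35.4%) were counted on miRNA genes. Replicate 2 held 11190481 reads, of which 5034257 (45.0%) were counted on miRNA genes.

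The miRNA counts of the gland came from few genes. Mir126a, an endothelial miRNA gene that lies within the vascular gene Egfl7, was the most abundant on the mean of the libraries and in replicate 1, and stood behind Mir122 in replicate 2, with a mean of 14.1% ± 0.116 of all miRNA counts (SD, n = 2). The SDs of shares depend on how much of the replicate 2 total Mir122 took. With Mir122 left out of the totals, a setting added after seeing the data, the share of Mir126a was 16.1% ± 2.57. Members of the let-7 family, which repress growth and cell-cycle regulators, held 19.3% ± 3.12 together, and 21.6% ± 0.136 with Mir122 left out. The 10 most abundant genes held 59.8% ± 5.77 of the counts (SD, n = 2), with 55.7% in replicate 1 (Wilson 95% interval 55.7 to 55.8) and 63.9% in replicate 2 (63.9 to 64.0). With Mir122 left out, the 10 most abundant held 57.4% ± 0.548. Of 2202 annotated miRNA genes, 358 had at least 10 counts in each library and 1411 had no count in either. On the mean of the libraries, 7 genes held 50% of the counts and 44 held 90%. Reads mapping to several places, 3002371 in replicate 1 and 2795730 in replicate 2, were set aside and enter none of these values. Ranks, shares and detection of genes with near-identical copies are therefore uncertain. A low count or a count of 0 for such a copy does not show that its miRNA is scarce in the gland. A count of 3, the limit that a count of 0 allows, stood for 0.790 CPM (counts scaled to a common library total) in replicate 1 and 0.596 CPM in replicate 2. Reads carried no molecular identifiers, so intervals and limits cover counting error only.

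After Mir126a, the mean ranking continued with Mir122, the main miRNA of hepatocytes, whose place rested on replicate 2 alone. Mir122 took 0.290% of counts in replicate 1 (Wilson 95% interval 0.284 to 0.295) and 21.5% in replicate 2 (21.4 to 21.5). Mirlet7g held 7.90% ± 0.672 of counts and Mir378a, which lies in an intron of the metabolic coactivator gene Ppargc1b, 7.14% ± 0.875 (SD, n = 2 for all shares). Mirlet7i held 4.22% ± 1.02, Mirlet7b 3.89% ± 0.758 and Mir143, a smooth muscle miRNA gene, 3.81% ± 1.03. Mir10a, encoded in the Hoxb region, held 2.76% ± 1.27. Mir375, known from endocrine cells such as those of the pancreatic islet, held 2.57% ± 1.14. Mir21a held 2.52% ± 2.30, Mir26b 2.25% ± 0.111 (2.57% ± 0.556 with Mir122 left out) and Mir22 1.92% ± 0.990. Mir126a and Mir378a each overlap an annotated miRNA gene on the opposite strand, Mir126b and Gm25301. In the counts made without regard to strand, Mir126a fell to 0.000352% and Mir378a to 0%, because reads over both genes were set aside as ambiguous.

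Coordinates are those of GENCODE M21 on mouse build mm10. Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 from 26591357 to 26591429 on the plus strand, overlapping an exon of Egfl7, and its hairpin reads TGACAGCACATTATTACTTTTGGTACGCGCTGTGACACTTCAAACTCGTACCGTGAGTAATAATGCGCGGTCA. Mir122 (ENSMUSG00000065402.1) lies on chromosome 18 from 65248861 to 65248926 on the plus strand, in an exon of the long noncoding RNA gene AC157910.3, with the hairpin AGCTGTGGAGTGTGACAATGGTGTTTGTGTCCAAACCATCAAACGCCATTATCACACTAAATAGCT. Mirlet7g (ENSMUSG00000065440.1) lies in an intron of Wdr82 on chromosome 9 from 106178840 to 106178927, with the hairpin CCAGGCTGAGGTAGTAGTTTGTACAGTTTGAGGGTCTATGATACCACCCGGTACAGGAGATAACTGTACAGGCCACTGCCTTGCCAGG. Mir378a (ENSMUSG00000105200.1) lies on chromosome 18 from 61397835 to 61397900 on the minus strand. Its hairpin reads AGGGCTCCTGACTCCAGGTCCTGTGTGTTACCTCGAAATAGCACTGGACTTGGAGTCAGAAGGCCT. Mir143 (ENSMUSG00000065445.3) is intergenic, on chromosome 18 from 61649196 to 61649258. Mir375 (ENSMUSG00000065616.3) is intergenic as well, on chromosome 1 from 74900658 to 74900721. Mir21a (ENSMUSG00000065455.1) lies on chromosome 11 from 86584067 to 86584158, overlapping an exon of Vmp1.

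**Figure D1:**
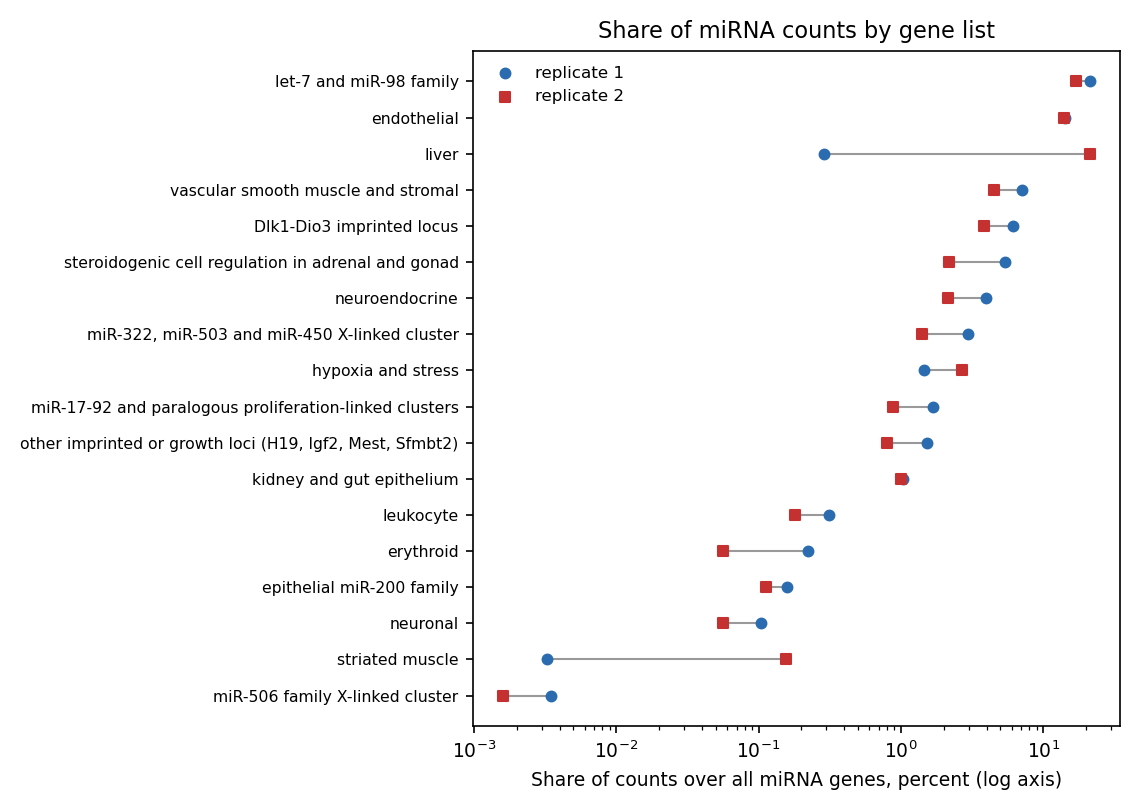
Share of all miRNA counts, in percent on a log axis, held by each of the 18 gene lists in replicate 1 (circles) and replicate 2 (squares), with a line joining the 2 values of a list. The liver list, which holds Mir122 alone, runs from 0.290% to 21.5%, and the striated muscle list from 0.00327% to 0.157%.

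By cell type and locus, the counts were led by the let-7 family, endothelium and, in replicate 2, the liver list. The endothelial list held 14.1% ± 0.116 of counts (SD, n = 2 for every share here), nearly all from Mir126a, and 16.1% ± 2.57 with Mir122 left out of the totals. Its opposite-strand partner Mir126b had 30 and 23 counts. The vascular smooth muscle and stromal list held 5.80% ± 1.82, led by Mir143 and by Mir10b at 14983 ± 7824 CPM. The imprinted Dlk1-Dio3 locus, whose miRNA genes are expressed from the maternal chromosome, had 47 of 58 members detected and held 5.02% ± 1.63. Its leading members Mir127, Mir411 and Mir379 stood at 10493 ± 3140, 9257 ± 5359 and 7843 ± 3148 CPM. The list of miRNA genes studied in steroid-producing cells of adrenal and gonad had all 17 members detected and held 3.80% ± 2.28. The neuroendocrine list held 3.06% ± 1.31, mainly from Mir375. The X-linked list of Mir322, Mir503, Mir351, Mir542 and Mir450b held 2.17% ± 1.09, with Mir322 at 1.86% ± 1.03. Its entry Mir450a matched no annotated symbol, so the neighbours Mir450-1 and Mir450-2 were left out.

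Markers of other cell types took smaller shares. The hypoxia and stress list held 2.08% ± 0.885, mostly from Mir22 (SD, n = 2 throughout). The proliferation-linked Mir17 to Mir92 clusters held 1.28% ± 0.563, with Mir93 at 3838 ± 2158 CPM and Mir17 at 3711 ± 1789 CPM. The growth-related loci around H19, Igf2, Mest and Sfmbt2 held 1.16% ± 0.510, mainly from Mir335, in an intron of Mest, at 1.02% ± 0.565. The kidney and gut list held 1.01% ± 0.0223, of which Mir30a, a gene expressed in many tissues, made up 0.889% ± 0.0838. With Mir122 left out, the kidney and gut list held 1.15% ± 0.168. Leukocyte genes held 0.246% ± 0.0944 and erythroid genes 0.140% ± 0.119. The leukocyte entry Mir146a matched no annotated symbol, so Mir146, with 4788 and 5669 counts, was left out. The leukocyte share is therefore that of an incomplete list. The epithelial miR-200 list held 0.136% ± 0.0329, mostly from Mir203 at 1107 ± 506 CPM. Neuronal genes held 0.0801% ± 0.0338. On the neuronal list, Mir9-1 and Mir9-3 share sequence with other annotated hairpins, and each had 0 and 1 counts. The numbered copies Mir9-2, Mir124a-1, Mir124a-2 and Mir124a-3 had 0 counts in both libraries. Reads mapping to several places were set aside, so shares of lists with such copies, let-7 among them, are uncertain and may be too low. Of the list for the X-linked miR-506 family, 2 of 21 members were detected, and it held 0.00255% ± 0.00135. One of these, Mir511, lies on chromosome 2 within Mrc1 and not in the X-linked cluster.

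Genomic clusters, defined as detected neighbours on 1 strand under 10 kb apart, numbered 47. They held 161 of the detected genes and 31.4% ± 6.11 of the counts (SD, n = 2). The pair of Mirlet7c-2 and Mirlet7b on chromosome 15 held 3.97% ± 0.744, and the pair of Mir145a and Mir143 held 3.96% ± 0.976. The distal Dlk1-Dio3 group on chromosome 12, from 109709060 to 109747960, counted 33 detected genes and held 3.28% ± 1.11. The Mir23b, Mir27b and Mir24-1 group on chromosome 13 held 2.27% ± 0.333.

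The 2 replicates had the same ranking of genes in broad terms, with a small set far apart. Mir122 was 99.8-fold higher in replicate 2 and Mir206, a miRNA of skeletal muscle, 74.6-fold higher. Mir192, of kidney, gut and liver, was 19.4-fold higher, and Mir483, in an intron of the growth factor gene Igf2, 18.9-fold higher. Mir26a-1 was 23.2-fold lower in replicate 2. Across the 358 detected genes, log2 CPM had a Pearson r of 0.959 and CPM a Spearman rho of 0.957, and genes are not independent replicates. Of 261 genes with a mean of at least 100 counts, 216 lay within 2-fold. The biological coefficient of variation estimated by edgeR was 0.444, and 0.352 without the 8 genes raised most, an estimate added after these had been seen.

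**Figure D2:**
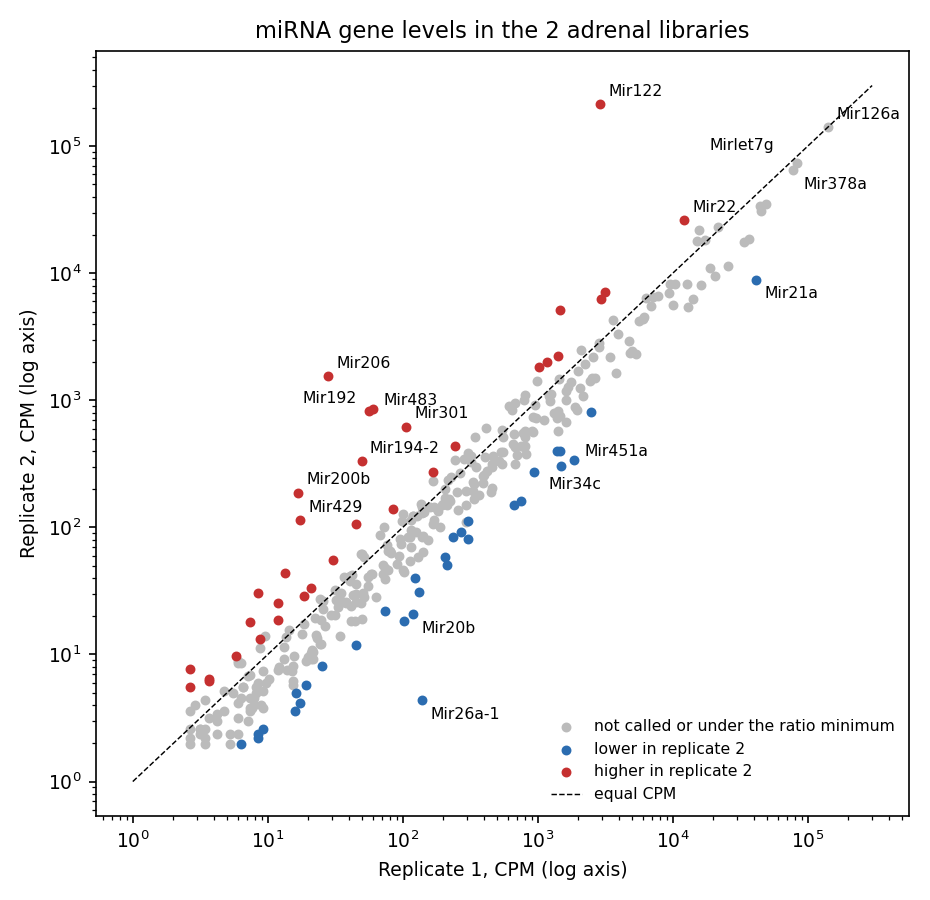
CPM of the 358 detected miRNA genes in replicate 1 (x, log axis) and replicate 2 (y, log axis). Red points are the 33 genes higher and blue points the 31 genes lower in replicate 2 by the exact binomial test after TMM scaling, grey points are the others, and the dashed line marks equal CPM; Mir122 and Mir206 lie farthest above it and Mir26a-1 farthest below it.

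The counts did not agree within sampling noise, as those of 1 library deposited in duplicate would, with a chi-square statistic of 1230156.2 on 422 degrees of freedom over 423 genes. In an exact two-sided binomial test of each gene's 2 counts, 33 genes were higher and 31 lower in replicate 2, at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 ratio of at least 1. Without the ratio minimum, 243 genes passed. Genes given below as not called include the 179 of these under the ratio minimum, which differed beyond counting error. The binomial test sets the reads of 2 libraries against each other and compares neither conditions nor animals. In edgeR's exact test 6 genes passed, with a dispersion estimated from the same 2 libraries, so that it gives no independent measure of the spread between replicates. They were Mir122, Mir206, Mir192, Mir483 and Mir200b above and Mir26a-1 below. With library totals in place of TMM scaling the median log2 ratio of all genes moved from -0.06 to -0.48, and the calls became 18 higher and 78 lower. Ratios are therefore given relative to the TMM scaling.

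Among the genes raised in replicate 2, Mir122 had a log2 ratio of 6.64 (95% counting interval 6.61 to 6.67), from 10996 and 1080041 counts. Mir206 had a log2 ratio of 6.22 (5.95 to 6.52), from 106 and 7815 counts, and lies on chromosome 1 from 20679010 to 20679082. Mir192 stood at 4.28 (4.08 to 4.49) and its neighbour on chromosome 19, Mir194-2, at 3.18 (2.96 to 3.41). Mir483 stood at 4.24 (4.05 to 4.44). Mir200b and Mir429, neighbours in an intron of Ttll10 and known for keeping the epithelial state, stood at 3.90 (3.54 to 4.30) and 3.13 (2.77 to 3.53). Mir301, in an intron of Ska2, stood at 2.98 (2.83 to 3.13). Adjusted p from edgeR's exact test was 0.00445 for Mir192 and 0.012 for Mir200b, and was 0.0865, 0.0919 and 0.115 for Mir194-2, Mir429 and Mir301.

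Among the genes lowered in replicate 2, Mir26a-1 had 530 and 22 counts and a log2 ratio of -4.54 (95% counting interval -5.25 to -3.95). It shares sequence with a second copy, Mir26a-2, which had 345 and 259 counts, so the value of either copy is uncertain. Mir20b and Mir106a, X-linked relatives of the Mir17 cluster, stood at -2.09 (-2.42 to -1.78) and -2.04 (-2.39 to -1.72). Mir451a, of red blood cells, stood at -2.03 (-2.11 to -1.95). Mir34c, a target of p53, stood at -1.87 (-1.96 to -1.79) and Mir21a, induced in many stress and injury settings, at -1.79 (-1.80 to -1.77). Mir376c of the Dlk1-Dio3 locus stood at -1.79 (-1.90 to -1.68). Gm26117, in the host gene Adgrb1, stood at -1.73 (-1.85 to -1.61). Mir26a-1 had an adjusted p of 0.00417 in edgeR's exact test, and the lowest among the other 7 was 0.879.

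**Figure D3:**
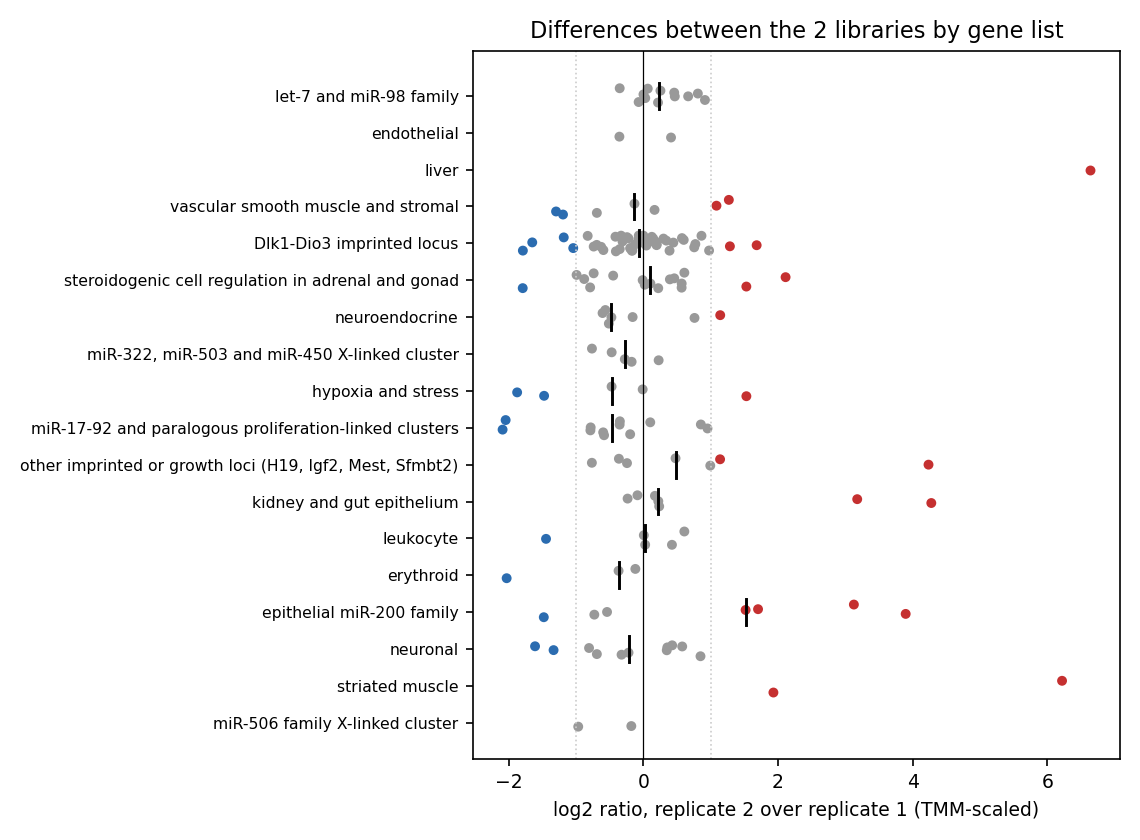
TMM-scaled log2 ratio, replicate 2 over replicate 1, of each detected member of the 18 gene lists, with points spread vertically within a list for legibility. Red and blue points passed the binomial test as higher or lower with an absolute log2 ratio of at least 1 (dotted lines), grey points did not, and black bars give the median of lists with at least 3 detected members, such as 1.52 for the epithelial miR-200 list.

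Of 14 lists with at least 3 detected members, 2 had a median outside the central 95% of 10000 random lists matched on expression. By chance, 0.7 would be expected if genes varied independently. Random lists were drawn gene by gene, while some lists hold neighbouring genes, such as Mir200b, Mir200a and Mir429. Neighbours that vary together would raise that expectation, so the percentiles may overstate how unusual a list is. The epithelial miR-200 list had a median log2 ratio of 1.52, at percentile 100, with 4 members higher, 1 lower and 2 not called. That median is the value of Mir205, from 45 and 128 counts. Mir205 and Mir203 are on the list but not at the loci of the miR-200 family. The members of the list did not move together. Mir200a, at 1.71, Mir205, at 1.52, Mir200b and Mir429 were higher. Mir141 was lower at -1.48, and Mir200c and Mir203 had log2 ratios of -0.73 and -0.54. The Mir17 to Mir92 list had a median of -0.47, at percentile 1.81, with 0 members higher, 2 lower and 10 not called. Most of its members had negative log2 ratios. The 2 called were Mir20b and Mir106a, at -2.09 and -2.04. Mir93, Mir106b, Mir17 and Mir20a stood at -0.78, -0.78, -0.59 and -0.58, and Mir25, Mir363 and Mir18 at -0.35, -0.35 and -0.19. The only positive members were Mir92-1, Mir19b-1 and Mir92-2, at 0.95, 0.86 and 0.10. These share sequence with other annotated hairpins, so their values are uncertain.

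Among the other lists, both detected members of the striated muscle list, Mir206 and Mir499 (log2 ratio 1.93, 0.96 to 3.15), were higher in replicate 2, and the other 8 of its 10 members were not detected. Of these, Mir1a-2, Mir1b and Mir133b share sequence with other annotated hairpins, so their low counts are uncertain. Mir1a-1, Mir133a-1 and Mir133a-2 had 0 counts in both libraries. They are numbered copies, whose reads may map to several places and be set aside. Their 0 counts thus do not show absence. In the kidney and gut list Mir192 and Mir194-2 were higher and 5 members were not called, with a median of 0.22 at percentile 81.95. The loci around H19, Igf2, Mest and Sfmbt2 had a median of 0.48 at percentile 94.96, with Mir483 and Mir675 higher and 5 not called. The let-7 family had a median of 0.24 at percentile 87.2 with all 12 members not called. In the steroidogenic list Mir125a (log2 ratio 1.53) and Mir383 (2.11) were higher, Mir21a was lower and 14 were not called, with a median of 0.11 at percentile 80.8. The medians of the let-7, kidney and gut, leukocyte and steroidogenic lists turned negative under library totals, at -0.19, -0.20, -0.40 and -0.31.

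The Dlk1-Dio3 list had 2 members higher, 4 lower and 41 not called, with a median of -0.07 at percentile 24.7. The smooth muscle and stromal list had 2 higher, among them Mir214 at 1.09, 2 lower and 3 not called, with a median of -0.13 at percentile 41.8. Of the leukocyte list only Mir142 was lower, at -1.44, and 4 were not called, with a median of 0.03 at percentile 61.3. Mir146, left out of that list, had a log2 ratio of 0.27. Mir451a was the 1 erythroid gene of 3 that was lower, and Mir144 and Mir486 had log2 ratios of -0.37 and -0.12, with a list median of -0.37 at percentile 16.4. The neuroendocrine list had 1 member higher and 6 not called, with a median of -0.47 at percentile 9.65. The hypoxia and stress list had Mir22 higher at 1.53, Mir34c and Mir34b lower and 2 not called, with a median of -0.47 at percentile 7.88. The neuronal list had 2 lower and 9 not called, with a median of -0.22 at percentile 39.4. The X-linked Mir322 list had all 5 members not called, with a median of -0.27 at percentile 21.3. No median was computed for the endothelial, striated muscle, liver and miR-506 lists, each with under 3 detected members. In the endothelial list Mir126a had a log2 ratio of 0.41, and in the miR-506 list Mir511 and Mir547 had -0.97 and -0.18, none of them called.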

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

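The tests on the genes raised in replicate 2, on pairs of genes and on shared sequence were chosen after the results had been seen, and the test of hairpin GC content was planned before its result. The opposite-strand column, outside the main measurement, held counts at genes with no annotated opposite-strand miRNA gene. Summed over all 2138 such genes, these counts came to 362 in replicate 1 and 257 in replicate 2. Mir203 alone gave 258 and 203 of them.

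The 8 genes raised most in replicate 2 include markers of liver, striated muscle and epithelium. Their smallest log2 ratio was 2.55 over 3 scalings. They were chosen as the largest ratios, and a scaling shifts all genes by about the same amount. The test could thus hardly have come out otherwise, and no conclusion on scaling is drawn from it. Striated muscle RNA may contribute: Mir499, Mir208b, Mir208a and Mir133b summed to 13 and 75 counts (lower bound of the log2 ratio 1.69), and all 9 members of the fixed list other than Mir206 to 18 and 86 (lower bound 1.53), but these sums include genes under the detection minimum, above which Mir499 alone remained. Liver RNA stays open. The 4 detected liver genes outside the pattern, also expressed in other tissues, had a median of 0.55 at percentile 93.43 of matched lists. Mir148a stood at 0.98 (2319 and 4509 counts) and Mir101b at -0.30 (5049 and 4030). The sum of all 5 liver genes, made up mostly of Mir101b and Mir148a, was 7464 and 8786 counts, a log2 ratio of 0.26 (0.21 to 0.30). The muscle sums took in genes under the detection minimum and the liver median did not, so these values do not rank the tissues. Mir802, the liver gene under the detection minimum, had 5 and 129 counts, and a rerun that let it in, made only after its counts had been seen and so given no weight, put the median at percentile 99.37. Whether liver was the only source cannot be told apart from several sources, since Mir206 (lower bound 5.95), which liver does not express, is itself one of the 8 genes, and tissue carried along at dissection, reads from other libraries of a multiplexed run and a difference between the animals were not tested.

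The spread between the replicates was examined over the 261 genes with a mean of at least 100 counts, the 8 raised genes included, for library preparation and for transcription or cell make-up. Pairs of similar sequence at distant loci had a median difference of log2 ratios of 0.572, against 0.697 for permuted pairs (permutation p = 0.0135, 349 pairs), and 0.447 within name families (permutation p = 0.0158), which is consistent with an effect of sequence in library preparation. Neighbouring genes of unlike sequence differed by 0.629 against 0.701 (permutation p = 0.2321, 582 pairs), and by 0.514 outside the Dlk1-Dio3 locus (permutation p = 0.0858), which decides nothing on transcription or cell make-up. Hairpin GC percent had a Spearman rho of 0.194 with the log2 ratio across 261 genes, between the limits set in advance. These 4 permutation p-values are unadjusted, and related genes that are regulated alike, or that share reads, would give the same closeness.

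In most of the genomic clusters compared here, gene copies with shared sequence had lower counts than their neighbours. Unlike the clusters above, these took in annotated genes named Mir whether detected or not, and were kept if any member was detected. Within 22 such clusters, members sharing at least 20 nt with another annotated hairpin had a lower CPM than members sharing none (median log2 difference -4.02, one-sided sign-flip permutation p = 0.00175). They were lower in 18 clusters and higher in 3. Loss of reads that map to several places may cause this, and low levels of these copies in the gland remain open. Of the detected genes 83 share such a run, among them abundant ones such as Mir378a and Mir411, and also Mir107, Mir376c, Mir26a-1 and Mir194-2, and these 83 held 15.3% and 13.5% of counts. No biological explanation was tested for this pattern.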

How the results depend on the processing

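Leaving out Mir122 was chosen after seeing the data, and the other settings named here were planned. List medians kept their side of the percentile limits in all 67 values recomputed under settings other than the scalings, which shift all genes by about the same amount and so hardly test this. Of all recomputed medians 8 changed sign, 4 of them through the common shift under library totals, and each lay inside the limits. The share of the 10 most abundant genes was 58.0% to 66.6% with 1 replicate left out. The summed share of all lists, 70.3%, became 65.4% without the most abundant gene and 66.5% without Mir122, which removes members from the sum. Detected genes numbered 588 at a minimum of 1 count, where the striated muscle list also had enough members and a median of 2.61 at percentile 100. At a minimum of 100 counts, 38 genes differed between the libraries, 18 higher and 20 lower in replicate 2, with fewer genes tested, and 37 of them were among the main 64. At that minimum 1 list lay outside the percentile limits, since the miR-200 list no longer had 3 members. Library totals alone gave 18 higher and 78 lower, and 49 of the main 64 genes remained. The edgeR exact test with the estimated dispersion, estimated from the same 2 libraries, called 6 genes, 5 higher and 1 lower, and 15 at an unadjusted p under 0.05. Leaving out a replicate leaves no ratio between libraries, so ratios and calls have no such value. No paired analysis was possible because the series has a single group. Genes with few counts are limited by depth: with 10 and 39 counts, the log2 ratio of Mir499 could lie anywhere from 0.96 to 3.15.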

Other observations

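The genes in this part were singled out after their values had been seen, and they are given as values only. The miR-200 family is encoded at 2 places, and its genes differed between the replicates by place. On chromosome 4, within Ttll10, Mir200b, Mir200a and Mir429 were all higher in replicate 2, with log2 ratios of 3.90, 1.71 and 3.13. On chromosome 6, Mir141 was lower at -1.48 (32 and 11 counts) and Mir200c had a log2 ratio of -0.73 (239 and 142 counts). The difference between the places was not tested.

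Neighbours within some other groups had like log2 ratios and within others unlike ones. Mir221 and Mir222 were both lower in replicate 2, at -1.34 and -1.65, as were Mir34c and Mir34b, at -1.87 and -1.47. On chromosome 17, Mir99b and Mir125a were higher in replicate 2 at 1.60 and 1.53, while Mirlet7e between them had a log2 ratio of 0.22. Mir145a was higher at 1.27 and its neighbour Mir143 stood at -0.13. Within Mir17hg, Mir17, Mir18 and Mir20a had log2 ratios of -0.59, -0.19 and -0.58, while Mir92-1 had 0.95 (3747 and 7148 counts), none of them called. In the Mir23a group on chromosome 8, Mir23a stood at 0.68 and Mir27a at -0.70, neither called. Within Dnm3os, Mir214 was higher at 1.09 and Mir199a-2 was lower at -1.29, with 73 and 29 counts for Mir199a-2. Mir92-1, Mir23a, Mir27a and Mir199a-2 share sequence with other annotated hairpins, so their values are uncertain.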
